A study of Mus musculus with 7 samples.

How the data were processed

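Single-cell RNA libraries were made with the 10x Chromium 3' v3 chemistry from sorted bone marrow cells of 7 mice, 4 given vehicle and 3 given STM2457. The submitters' processing notes name Cell Ranger 6.0.1 and the mouse build mm10 for every library. The annotation release given to Cell Ranger is not given in the sources used here.

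The deposited files analysed here are text lists without values. Each barcode file holds 1 barcode of 16 bases with the suffix -1 per line, sorted and without repeats. Each gene file holds an Ensembl identifier, a symbol and a feature type per line. None of these files holds a count, a normalized value or a score. Count matrices and the processed object that the labels name were not analysed here, so the depth of each library is unknown, cells could not be called, doublets could not be assessed or removed, and no interval or detection limit for a gene can be given. What decides whether a barcode enters the unfiltered lists of experiment 2 is not given in the sources used here.

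Tests of gene expression on counts summed per library, with experiment as a covariate, tests per cell class, shares of cell classes and gene list tests had been planned before the data were examined. They need counts and were not run. The rule for named genes also rested on those tests; with no counts, genes are named only as members or non-members of the gene lists, first the m6A genes and then the other lists fixed before the data were examined, and genes outside those lists are marked as chosen afterwards or given as the gene used for the sort.

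Lists were compared in Python 3.11.15 with NumPy 2.4.6. Libraries were grouped by treatment and experiment from their titles. Barcodes were compared as exact 16-base sequences. The planned difference in listed barcodes between STM2457 and vehicle was estimated by least squares with an experiment term, and tested by exact permutation of the treatment labels within experiments, two-sided, at a threshold of 0.05. Each mouse gave 1 library, so n counts mice. Overlap was measured as the Jaccard index and as the ratio of shared barcodes to an independent expectation. That expectation takes both lists as independent draws from the full list with the same chance for every barcode. In 2 simulated sets of lists, the partner function recovered the known share of pairs with exactly 1 barcode listed. The overlap ratio was near its known value of 1 for independent draws. With 1 partner favoured it was checked only to be well above 1. The Jaccard index was not checked in simulation. The self-test of differential expression was not needed because no such test was run.

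Gene identifiers were matched without version suffixes to GENCODE M21, which annotates GRCm38, the assembly that mm10 names. Of the identifiers of experiment 1, 30934 of 31053 had an entry there, and of those of experiment 2, 32158 of 32285. Coordinates are 1-based and come from that annotation; the gene lists give none. Gene types are those of GENCODE M21 and cover only matched identifiers. Alternatives were experiment 2 alone, barcodes listed in a single library, the label number as a block, leaving out each library in turn and, added after the lists were seen, another measure of overlap.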

Results

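The series addressed what pharmacological inhibition of METTL3 does to normal blood formation in the mouse. METTL3 is the catalytic subunit of the complex that methylates adenosine in messenger RNA at the N6 position (m6A), and STM2457 is a small-molecule inhibitor of it. Female C57BL6 mice received STM2457 at 50 mg/kg or vehicle by daily intraperitoneal injection for 14 days, and 20000 bone marrow cells without lineage markers and positive for the receptor KIT (a gate that holds haematopoietic stem and progenitor cells) were sorted per mouse for droplet-based single-cell RNA sequencing. The 7 libraries, each from 1 mouse, fell into 2 experiments. Experiment 1 held 2 vehicle libraries and 1 STM2457 library, and experiment 2 held 2 of each.

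The files analysed here were, for each library, the list of cell barcodes and the list of genes that name the columns and rows of an unfiltered count matrix. The matrices themselves were not analysed here. No UMI count, sequencing depth, cell number, cell type or expression level was therefore measured for any gene, and the comparisons of expression and of cell classes between STM2457 and vehicle that the design implies were not made. No result below is evidence for or against an effect of STM2457 on blood progenitors.

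Genes of the m6A machinery were looked up in the gene lists of both experiments. All 15 genes of a list of m6A writers, readers and erasers were in both gene lists. Mettl3 (ENSMUSG00000022160), the drug's target, lies on chromosome 14 from 52294841 to 52305128 on the minus strand of mm10 in the GENCODE M21 annotation. Its partner in the methyltransferase complex, Mettl14 (ENSMUSG00000028114), lies on chromosome 3 from 123368297 to 123386108. The demethylase genes Fto (ENSMUSG00000055932, chromosome 8, 91313525 to 91668439) and Alkbh5 (ENSMUSG00000042650, chromosome 11, 60536381 to 60558512) were also in both. Kit (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722), which encodes the receptor used for the sort, was in both lists. A gene in these lists was a target of counting, which does not show that it was detected.

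The lists of lineage markers were equally represented. All 8 stem and multipotent progenitor markers (among them Procr, Hlf and Mecom), all 8 erythroid markers (among them Gata1, Klf1 and Epor), all 6 megakaryocyte markers (among them Pf4 and Itga2b) and all 6 neutrophil progenitor markers (among them Mpo and Elane) were in both gene lists. So were all 7 monocyte and dendritic markers, all 5 basophil and mast cell markers, all 3 eosinophil markers, all 7 lymphoid progenitor markers and all 18 markers of other cells that the gate could hold. The 9 p53 targets, 7 transcripts described as METTL3-dependent in leukaemia, 7 S phase genes, 6 G2/M genes, 6 haem synthesis genes and 5 immediate early stress genes were complete in both as well.

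One gene of the fixed lists separated the experiments. Mx1 (ENSMUSG00000000386), an interferon-induced antiviral GTPase gene on chromosome 16 from 97447035 to 97462907, was in the gene list of experiment 1 and was absent, by identifier and by symbol, from that of experiment 2. The other 13 of 14 interferon-stimulated genes, among them Isg15, Ifit1 and Irf7, were in both. Over all 137 genes of the lists, 137 were in the list of experiment 1 and 136 in that of experiment 2.

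The experiments had different gene lists, and the libraries within each experiment had the same one. Experiment 1 listed 31053 genes and experiment 2 listed 32285, of which 30406 identifiers were shared. Of the shared identifiers, 597 had a different symbol in the other experiment. In experiment 1, 647 identifiers were unshared, and 605 of them had an entry in GENCODE M21, including 312 protein-coding genes and 247 long intergenic non-coding RNA genes (lincRNAs). In experiment 2, 1879 identifiers were unshared and 1829 had an entry, including 710 processed transcripts, 393 lincRNAs, 327 sense-intronic transcripts and 40 protein-coding genes. By contrast, the 30329 shared identifiers with an entry included 10 processed transcripts, 5212 lincRNAs and 21585 protein-coding genes, and sense-intronic transcripts were absent. Processed and sense-intronic transcripts were thus found almost only in the list of experiment 2. Non-coding RNAs from bidirectional promoters had the same pattern, with 175 unshared in experiment 2 and 14 shared. The unshared lincRNAs and protein-coding genes were of types that were also abundant among the shared identifiers. After identifiers whose symbol was in the other list under another identifier were set aside, 296 protein-coding genes remained for experiment 1 and 28 for experiment 2. A gene whose identifier and symbol both changed would stay in these counts. Only 35 of the 296 and 14 of the 28 had a given name, and the rest had Gm, Rik or clone-type symbols. Examples, chosen after the lists were seen, are Raver1 (chromosome 9), Tymp (chromosome 15) and Rbm12 (chromosome 2) in experiment 1, and Apbb3 (chromosome 18), Itprip (chromosome 19) and Tmem223 (chromosome 19) in experiment 2.

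The barcode lists of experiment 1 carried no information on treatment. The 3 lists were identical, at 6794880 barcodes each. The 4 lists of experiment 2 were different subsets of that full list, and 0 of their barcodes lay outside it. The vehicle libraries listed 3509855 barcodes (replicate 1, 51.7% of the full list) and 3666440 barcodes (replicate 2, 54.0%). The STM2457 libraries listed 3565580 (replicate 1, 52.5%) and 3736643 (replicate 2, 54.99%). These numbers far exceed the 20000 cells sorted per mouse, so most listed barcodes cannot stand for a sorted cell.

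**Figure D1:**
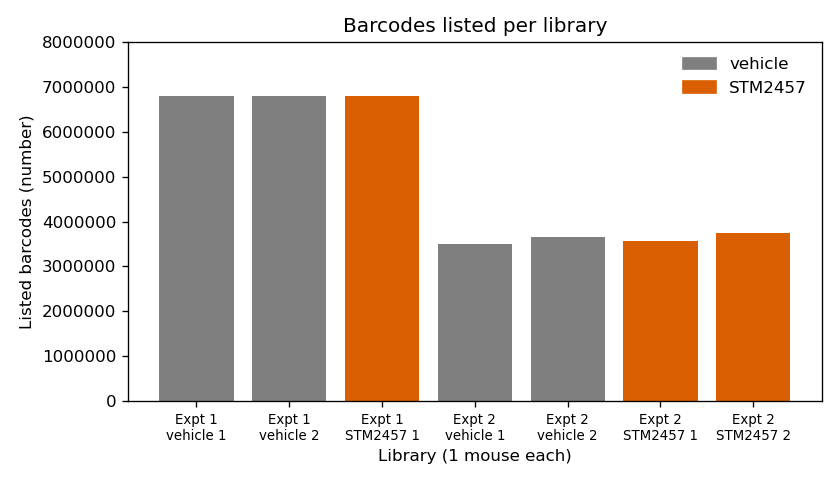
Number of barcodes listed per library (vertical axis, from 0), with 1 bar per mouse, vehicle in grey and STM2457 in orange. The 3 libraries of experiment 1 hold the same 6794880 barcodes, and the 4 libraries of experiment 2 lie between 3509855 and 3736643, with the treatments interleaved.

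In experiment 2 the number of listed barcodes did not separate the treatments. It was 3588147.5 ± 110722.3 (SD, n = 2) for vehicle and 3651111.5 ± 120959.8 (SD, n = 2) for STM2457. The difference of 62964 barcodes, or 1.75% of the vehicle mean, was smaller than either SD. A two-sided exact permutation test over the 6 arrangements of the labels gave p = 0.667, and the smallest p that it allows is 0.333. In the planned comparison over all 7 libraries with an experiment term the difference was 37778.4 barcodes, with p = 0.667 over 18 arrangements (two-sided exact permutation test). The arrangements of experiment 1 all give the same value, so the smallest p this test allows is also 0.333, and no outcome could have passed the threshold. The difference is diluted by experiment 1, where the difference is 0 because the lists are identical.

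The overlap of the barcode lists was close within and between treatments. Across the 6 pairs of experiment 2 libraries, 3083458 to 3367224 barcodes were shared, a Jaccard index (shared barcodes over barcodes in either list) of 77.2% to 83.4%. The mean index was 80.3% for the 2 pairs within a treatment and 80.3% for the 4 pairs between treatments, a difference of -0.0042 percentage points. A two-sided exact permutation test over the 3 splits of the libraries into pairs gave p = 1.00, where 0.333 is the smallest possible. This comparison was added after the lists were seen.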

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

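None of the exact permutation tests of listed barcodes or of their overlap could have passed the threshold under any setting, since the smallest p they allow is 0.333, or 0.50 with the block, so their p-values say nothing about stability. The direction of the difference is not stable. Over all 7 libraries it was 37778.4 barcodes higher with STM2457; leaving out 1 library at a time gave -11283.8 to 74247.7. It turned negative without the STM2457 replicate 2 of experiment 2 (-11283.8) and without the vehicle replicate 1 of experiment 2 (-7664.2), and it was 62964 in experiment 2 alone or without the STM2457 library of experiment 1. Barcodes listed in a single library of experiment 2 are another measure, on a smaller scale. Their number was 137462.5 ± 6794.6 (SD, n = 2) for vehicle and 135411.5 ± 7481.9 (SD, n = 2) for STM2457. That difference, -2051, had the opposite sign and was smaller in size than either SD. Its cause was not tested. With the label number as a replicate block in experiment 2 the mean paired difference was 62964, from 55725 for number 1 and 70203 for number 2 (exact permutation p = 0.50 over 4 sign changes). The labels do not say that a shared number marks shared handling, and with 2 pairs the data cannot show it. The overlap within minus between treatments, -0.0042 percentage points as a Jaccard index, became 0.00038 as a ratio to independent draws, an alternative chosen after seeing the data (exact permutation p = 0.667 over 3 splits). The alternatives set beforehand for expression, cell classes and gene lists were not run, because they need counts.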

Other observations

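Of the tests in this part, the one of independent draws was chosen after its result was seen; the one of partner barcodes was fixed before. The full list had an internal structure. Each of its 6794880 barcodes had a partner in the list that differs only by the complement of bases 8 and 9, counted from 1 at the first base of the barcode, which gives 3397440 pairs. In experiment 2, exactly 1 barcode of the pair was listed for 79.1% of pairs in vehicle replicate 1, 81.4% in vehicle replicate 2, 80.3% in STM2457 replicate 1 and 82.9% in STM2457 replicate 2, against 49.5% to 49.9% if listing were independent of the partner. In 1869324 pairs (55.02%), 1 barcode was in all 4 libraries and its partner in none. In 4.93% of pairs both were in all 4, and in 0.236% neither was in any.

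Why each library of experiment 2 listed about 52% to 55% of the full list was weighed against both readings. Independent draws in which every barcode of the full list has the same chance are argued against by the overlap of the libraries. The lowest ratio of shared barcodes to the independent expectation was 1.67 over the 6 pairs, where such draws give a ratio near 1. Simulated lists drawn independently but favouring 1 barcode of each pair also gave a ratio well above 1. The ratio therefore does not argue against independent draws of that kind, and it cannot separate them from the partner structure. The partner structure is consistent with the pattern, since the lowest share of pairs with exactly 1 barcode listed was 79.1%. It does not cover every pair, since both barcodes were listed in 410435 to 459590 of the 3397440 pairs per library. Neither barcode was listed in a further 120387 (STM2457 replicate 2) to 298020 (vehicle replicate 1) pairs per library. The lists hold no value per barcode, so what sets the members of a pair apart cannot be told from them. No biological explanation was tested. Both treatments show the pattern, which bears only on an effect of the treatment.

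The experiments differ in the gene list and in whether the full barcode list was written, although the processing notes give 1 Cell Ranger version for all libraries. Both experiments contain vehicle and STM2457 libraries. Within each experiment, these had the same gene list and were alike in whether the full barcode list was written. The difference therefore follows the experiment and not the treatment. Joining counts across the experiments on identifiers would leave 30406 genes, and Mx1 would be left out of an interferon comparison.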
